A study of Mus musculus with 28 samples.

How the data were processed

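The series held bulk RNA-seq of mouse embryonic stem (ES), trophoblast stem (TS), primitive endoderm stem (PrES) and extraembryonic endoderm (XEN) cell lines, of PWKB6NF1 (PBF1) lines labelled PrES and PrES-to-XEN, and of cells labelled XEN-like. The deposited file was 1 table of estimated counts per gene symbol. Per the labels, kallisto 0.46.2, Trim Galore 0.6.4 and bcl2fastq 2.20.0.422 were used with build mm10, with no role or order stated. The annotation, the kallisto options, the way transcripts were summed to symbols and the rounding were not stated, and every cell held a whole number. The values were not scaled to a common total. Of 28 columns 24 were used. The other 4, all TS libraries, were 0 in every cell and were left out, so TS cells had 2 lines where the labels and the plan name 6. The plan also allowed for TPM, and the tests for counts were used. In the columns used, 4257 symbols had no count. Library totals ranged from 9348219 to 29067854. The floor for a gene without counts was 3 counts over the group, and floors and intervals cover counting error only.

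Cell types were compared with 1 value per line. Libraries of 1 line and type, such as the 2 media of an ES or XEN line or the 2 passages of 1 PrES line, were summed, which gave 19 values: 2 ES, 2 TS, 6 PrES, 2 XEN, 2 PBF1 PrES, 2 PBF1 PrES-to-XEN and 3 XEN-like. All types were fitted together in edgeR 4.0.16 (R 4.3.3) with its quasi-likelihood test, TMM scaling, filterByExpr (19512 genes kept) and robust, trended dispersion. The 2 comparisons of media used the 24 libraries in 9 groups (19289 genes kept). P-values were adjusted by Benjamini-Hochberg over all genes of a comparison, and a gene was called at adjusted p under 0.05 with a log2 fold change of at least 1 in size. Standard errors are the log2 fold change divided by the square root of the F statistic. P-values measure the spread between these lines, so they do not extend to the strains. ES lines were B6N129X1F1 and the other types CD-1, apart from PBF1, so ES and PrES cells differed in strain as well as in type. All ES libraries carried 2iL in their names, all XEN libraries Serum and all XEN-like libraries Wnt3a, while PrES libraries named no medium. Medium therefore cannot be told apart from type in those comparisons either.

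Before the data were examined, the comparisons, the groups, 30 gene lists with their lead members and most alternatives were fixed. Lists were tested by camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists of a comparison. Fry was run as well and is not reported. Each list also has its number of genes called, and its number with adjustment over the list alone. Genes were named by a rule. For each comparison the 6 largest increases and the 6 largest decreases among called genes were taken (4 each way for the media and for XEN-like against XEN cells), with a mean of at least 10 CPM in the higher group and the same direction in every line, leaving out predicted and unnamed genes. To these came the lead members of each list described and up to 3 further members with the smallest adjusted p. Genes in the list are counted under both. Where list members were at 0 counts in a whole group, the median is given also with those genes at their bound. Coordinates were taken from GENCODE M21.

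Concordance of fold changes was measured by Pearson's r, and overlap of calls was set against the number given by independence. A library's position between PrES and XEN was its projection of log2 CPM onto the line between the 2 means, with its own line left out. The difference of the XEN-ward change between CD-1 and PBF1 was tested as an interaction in the same fit. The method was tested on simulated data built from these libraries. There 75% to 92% of genes with a 4-fold change and 93% to 99% of genes with an 8-fold change were recovered. False calls numbered 5 to 11 among 18706 to 18929 unchanged genes. Each simulation changed only 100 genes 4-fold and 100 genes 8-fold, while 7883 genes were called between XEN and PrES cells. The figures therefore do not measure recovery or false calls where so many genes change. ES against PrES and TS against PrES cells were not simulated. Within groups no 2 libraries were copies of each other, with a chi-squared per degree of freedom of at least 20.1 over 31 pairs. Libraries that carry the same line name in 2 groups pair the samples of the media comparisons and of the PBF1 comparison. Their deviations from the group means correlated by 0.068 (ES), 0.387 (XEN) and 0.0395 (PBF1), and the line was used as a block in an alternative fit.

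The alternatives were median-ratio, total-count and quantile scaling, no filter, a filter on mean CPM of at least 5, no trend and robust step, DESeq2 1.42.0, only the 2 groups compared, every library as its own replicate, 1 medium or passage range alone, the line as a block, and each line or library left out in turn. Where 1 sample was left in a group, it was assumed to vary like the other groups. Alternatives that needed TPM (added values of 0.1 and 5 in place of 1, and filters on mean TPM) could not be run on counts as planned, and the CPM filter and a prior count of 0.1 for the position replaced them. Quantile scaling had been planned on TPM, and for the calls its form on counts, limma on quantile-scaled log2 CPM, was chosen later, as were total-count scaling and the CPM filter. Other alternatives chosen later left out genes that follow the fibroblast level, and used only PrES libraries of low or of high Malat1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.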

Results

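The deposited table held estimated RNA-seq counts per gene symbol for 28 bulk libraries of mouse stem cell lines. It contained counts in 24 of them. Embryonic stem (ES) cells gave 4 libraries from 2 lines, each line in 2 media (FBS/2iL and NB/2iL as written in the labels). Trophoblast stem (TS) cells gave 2 libraries with counts, 1 per line, and the other 4 TS columns were 0 in every cell and were not used. Primitive endoderm stem (PrES) cells of the CD-1 strain, the cells named in the study's title, gave 7 libraries from 6 lines at passages 12 to 41. Extraembryonic endoderm (XEN) cells gave 4 libraries from 2 lines, each line in Serum/L and Serum/C3L. A second strain, labelled PWKB6NF1 and named PBF1 in the titles, gave 2 PrES lines and the same 2 line numbers again as PrES-to-XEN. Cells labelled XEN-like carried Wnt3a in their names and gave 3 libraries from 3 lines. Total counts per library ranged from 9348219 to 29067854. The floor used for a gene with no counts was 3 counts summed over a group, and floors and intervals cover counting error only. Values below given as mean ± SD across lines are CPM (counts scaled to a common library total with TMM factors). Log2 fold changes (log2FC) are given ± standard error. There were n = 2 lines for ES, TS, XEN, PBF1 PrES and PBF1 PrES-to-XEN cells. For PrES cells n = 6 and for XEN-like cells n = 3. CPM of Malat1, Col1a1, Xist, Ddx3y and Uty in single libraries are counts scaled to the library total alone, without TMM factors.

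All 24 libraries correlated best with the mean of their own cell type when their own line was left out, and the first 2 principal components held 30.7% and 21.1% of the variance. Gata6 (chromosome 18, 11052064 to 11085635, build mm10) was at 271 ± 31.6 CPM in PrES, 468 ± 48.4 in XEN, 0.963 ± 0.546 in ES and 3.17 ± 1.02 in TS cells. Pou5f1 (chromosome 17, 35506018 to 35510772) was at 585 ± 99.2 CPM in PrES and 938 ± 23.6 in ES cells, against 0.239 ± 0.0633 in XEN and 0.409 ± 0.471 in TS cells. Nanog (chromosome 6, 122707489 to 122714633) was at 1.69 ± 0.490 CPM in PrES and 601 ± 32.5 in ES cells. PrES cultures therefore held both Gata6 and Pou5f1 RNA, with little Nanog. Bulk libraries do not show whether the same cells held both.

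**Figure D1:**
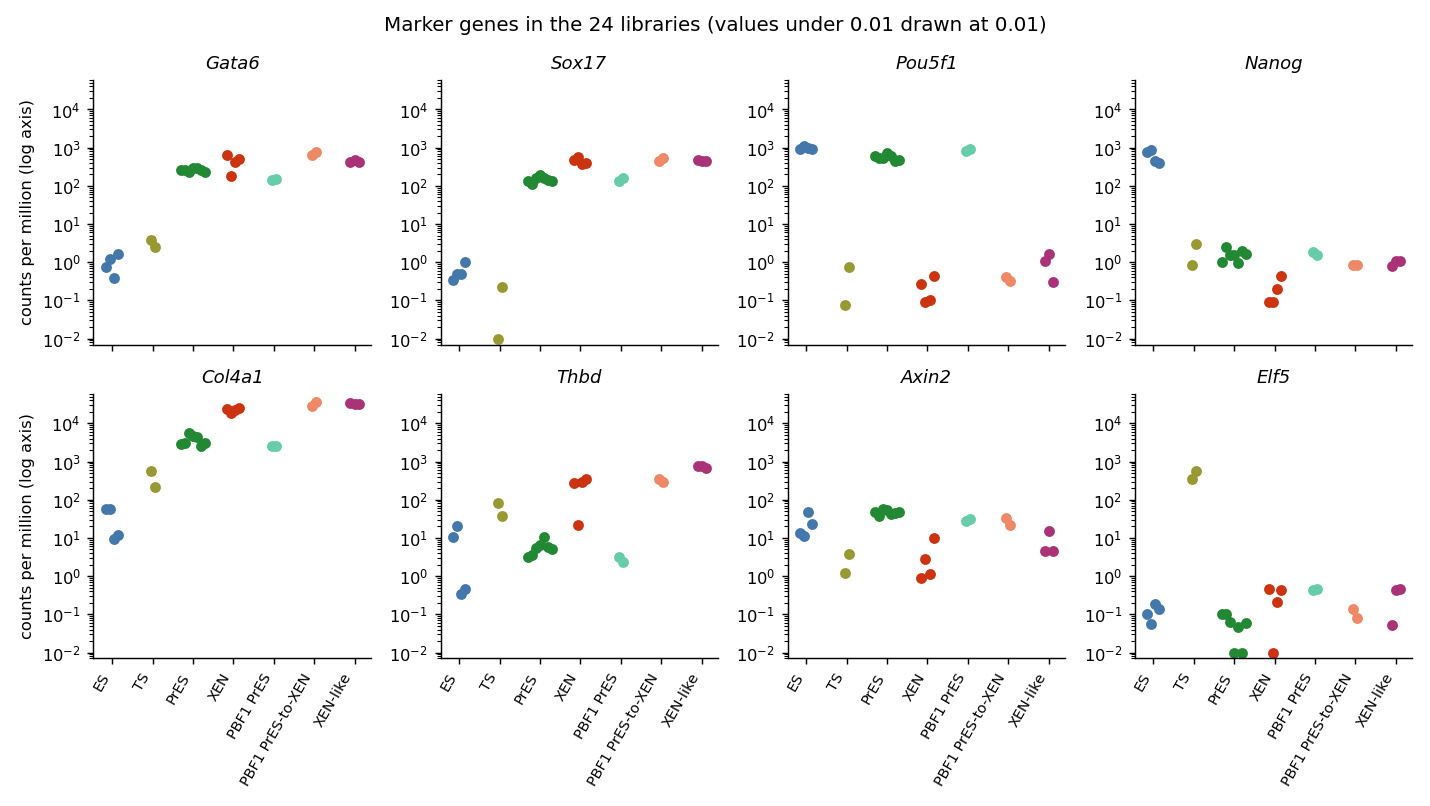
CPM (log axis) of 8 marker genes in each of the 24 libraries, grouped by cell type, 1 point per library. Gata6 and Pou5f1 were both above 100 CPM only in the CD-1 and PBF1 PrES libraries, and Col4a1 was highest in XEN, PBF1 PrES-to-XEN and XEN-like libraries.

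The comparison of XEN with PrES cells asked how the 2 endoderm stem cell types of the same strain differ. All XEN libraries were in media named Serum and PrES libraries named no medium, so medium cannot be told apart from type here. The parietal endoderm list moved up in XEN cells, with a median log2FC of 2.25 over 17 genes, 13 called higher and 1 lower, and 15 adjusted over the list alone. For parietal endoderm genes, camera gave adjusted p = 1.1e-13, and adjusted p = 0.0184 with an estimated correlation. Thbd rose from 6.28 ± 2.62 to 249 ± 134 CPM (log2FC 5.30 ± 0.34, edgeR adjusted p = 1.9e-08), Fst from 5.26 ± 0.668 to 794 ± 66.8 CPM (7.24 ± 0.34) and Plat from 36.4 ± 11.5 to 390 ± 114 CPM (3.42 ± 0.29). Vim fell by 2.00 ± 0.38 on the log2 scale within the same list. The basement membrane genes on that list and their own list rose with them. Lama1 (chromosome 17, 67697259 to 67822647) went from 2691 ± 525 to 15580 ± 1946 CPM (2.53 ± 0.18, edgeR adjusted p = 4.4e-08), Lamc1 from 1555 ± 337 to 13710 ± 1143 (3.14 ± 0.20) and Col4a1 (chromosome 8, 11198423 to 11312826) from 4080 ± 1240 to 24140 ± 1932 (2.56 ± 0.28). Over the 19 basement membrane genes the median was 1.69, with 12 called higher and 2 lower and 14 adjusted over the list alone. For basement membrane genes, camera gave adjusted p = 1.0e-06, and adjusted p = 0.118 with an estimated correlation. Secretory chaperones moved the same way: Hspa5 rose by 2.12 ± 0.24, Calr by 2.08 ± 0.20 and Pdia4 by 2.10 ± 0.24, while Ddit3 fell by 1.70 ± 0.35. The unfolded protein response list had 8 of 15 genes called higher and 2 lower, 10 adjusted over the list alone (median 1.05). For unfolded protein response genes, camera gave adjusted p = 0.00301, and adjusted p = 0.394 with an estimated correlation.

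Among primitive endoderm genes, Gata4 rose from 267 ± 27.9 to 1025 ± 37.4 CPM (log2FC 1.94 ± 0.13), Sox17 (chromosome 1, 4490931 to 4497354) by 1.66 ± 0.22 and Foxa2 by 2.31 ± 0.18, whereas Gata6 (0.78 ± 0.20) and Pdgfra (0.54 ± 0.27) stayed under the minimum of 1. The FGF receptor genes fell, Fgfr1 from 55.2 ± 13.4 to 2.04 ± 1.93 CPM (-4.78 ± 0.74) and Fgfr2 from 98.6 ± 29.5 to 19.7 ± 3.13 CPM (-2.32 ± 0.42). Of the 15 primitive endoderm genes 4 were called higher and 2 lower, 6 adjusted over the list alone (median 0.78). For primitive endoderm genes, camera gave adjusted p = 0.0153, and adjusted p = 0.338 with an estimated correlation. Visceral endoderm genes divided: Rbp4 (9.45 ± 0.85), Ttr (6.56 ± 0.68), Spink1 (7.25 ± 0.84) and Mttp (2.57 ± 0.33) rose, and Amn (-4.74 ± 0.83) and Cubn (-1.44 ± 0.30) fell. That list had 12 of 22 genes called higher and 3 lower, 15 adjusted over the list alone (median 1.38). It was not called without XEN line 1M (median 0.67) or with only the Serum/C3L libraries of XEN (median 1.34). For visceral endoderm genes, camera gave adjusted p = 0.0238, and adjusted p = 0.492 with an estimated correlation. Among endocytosis receptor genes 3 of 14 rose and 3 fell, 6 adjusted over the list alone (median 0.26, below 0 with total-count scaling or the filter on mean CPM), with Lgmn (1.91 ± 0.24) and Clcn5 (1.47 ± 0.15) higher and Fcgrt (-6.04 ± 0.98) lower.

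Pluripotency, Wnt and germline genes were lower in XEN cells. Pou5f1 fell by 11.24 ± 0.64 on the log2 scale (edgeR adjusted p = 5.2e-09), Esrrb from 94.9 ± 38.9 to 0.239 ± 0.0633 CPM (-8.61 ± 0.60), and Dppa4 (-6.97 ± 0.47) and Utf1 (-5.57 ± 0.47) were lower as well. Of the 22 naive pluripotency genes 16 were called lower and 0 higher, 16 adjusted over the list alone (median -4.48, or -3.86 with genes at 0 set to their bound). For naive pluripotency genes, camera gave adjusted p = 1.2e-11, and adjusted p = 0.00424 with an estimated correlation. Axin2 (chromosome 11, 108920349 to 108950783) fell from 48.2 ± 7.21 to 3.86 ± 2.65 CPM (-3.65 ± 0.58) and Ccnd1 from 171 ± 73.7 to 0.867 ± 0.423 CPM (-7.59 ± 0.96), with Nkd1 (-5.69 ± 0.88) lower too. Of the 17 Wnt targets 11 were called lower, 11 adjusted over the list alone (median -3.54, or -2.17 at the bound). For Wnt target genes, camera gave adjusted p = 0.00231, and adjusted p = 0.254 with an estimated correlation. Germline genes at low levels in PrES cells were called lower for 12 of 16, also 12 adjusted over the list alone (median -4.72), with Sycp3 at 9.28 ± 5.48 against 0.105 ± 0.0116 CPM. For germline genes, camera gave adjusted p = 0.00501, and adjusted p = 0.338 with an estimated correlation. Dnmt3l fell from 209 ± 46.0 to 1.2 ± 1.05 CPM (-7.41 ± 0.62), with Tet2 (-3.80 ± 0.36) lower too. The 9 DNA methylation genes split into 5 lower and 2 higher, 7 adjusted over the list alone (median -1.40), and the list was not called (camera adjusted p = 0.289) except by camera on DESeq2 values.

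Feedback genes of the FGF and ERK pathway were lower in XEN cells for 9 of 18 and higher for 0, 9 adjusted over the list alone (median -0.91). Fosl1 (-5.68 ± 0.63) and Spred3 (-3.68 ± 0.43) were among those lower. The lead gene Etv5 was not called, though it was with only the Serum/C3L libraries of XEN (log2FC -1.28). For this list camera gave adjusted p = 0.0212, and adjusted p = 0.254 with an estimated correlation, and it was not called without XEN line 2F (median -0.83).

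Cell cycle genes were somewhat higher in XEN cells: Mcm2 rose from 120 ± 18.7 to 422 ± 2.63 CPM (log2FC 1.81 ± 0.13) and Cdk1 by 1.56 ± 0.17, and 8 of 21 were called higher, 8 adjusted over the list alone (median 0.89). For cell cycle genes, camera gave adjusted p = 1.2e-06, and adjusted p = 0.355 with an estimated correlation. Imprinted genes went both ways, 7 of 29 higher and 9 lower, 16 adjusted over the list alone (median -0.05). Among them Zrsr1 (chromosome 11, 22972005 to 22976496) fell from 272 ± 19.2 to 22.4 ± 2.24 CPM (-3.61 ± 0.18), Meg3 was lower (-8.18 ± 0.94) and Sgce rose by 3.47 ± 0.22. Fibroblast collagens nearly disappeared in XEN libraries. Col1a1 was at 2136 ± 888 CPM in PrES and 2.40 ± 0.226 in XEN cells (-9.80 ± 1.54, edgeR adjusted p = 1.1e-04), Col6a3 at 599 ± 147 and 0.105 ± 0.0116 (-12.41 ± 1.14), and Col3a1 at 433 ± 233 and 0, at least 5514-fold lower. All 16 fibroblast genes were called lower, 16 adjusted over the list alone (median -9.82, or -8.80 at the bound). For fibroblast genes, camera gave adjusted p = 1.9e-08, and adjusted p = 0.328 with an estimated correlation. Mesenchymal genes fell with them, 10 of 16, also 10 adjusted over the list alone (median -2.30), led by Fn1 from 2463 ± 322 to 116 ± 2.70 CPM (-4.41 ± 0.53) and Mmp2 (-6.44 ± 0.95). For mesenchymal genes, camera gave adjusted p = 0.00541, and adjusted p = 0.473 with an estimated correlation. So did 12 of 13 interferon response genes, 12 adjusted over the list alone (median -5.35, or -3.67 at the bound), for example Ddx58 from 25 ± 3.85 to 1.96 ± 0.118 CPM (-3.67 ± 0.34). For interferon response genes, camera gave adjusted p = 2.2e-04, and adjusted p = 0.355 with an estimated correlation.

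In total 7883 of 19512 genes were called between XEN and PrES cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2292 higher and 5591 lower in XEN. The share called higher was 29.1% with TMM scaling, 17.3% of 8045 with total counts as library sizes and 52.0% of 5855 with quantile scaling, where the median of all genes shifted by -0.33 and 0.44 on the log2 scale. Against the 2 PrES libraries with the low Malat1 level of XEN libraries, 4765 genes were called, 40.3% of them higher. The largest increases under the rule for named genes were Gkn2 (12.66 ± 0.81), Myh7 (10.90 ± 0.48), Nepn (10.80 ± 0.58), Rbp4, Gkn1 and Pdyn, the last at least 3074-fold over 0 counts in PrES cells but at 85.2 ± 118 CPM in XEN cells, so that 1 of the 2 lines carried most of it (log2FC 8.46 without XEN line 1M and 14.81 without 2F). The largest decreases were Col3a1, Tfap2b (at least 594-fold), Thy1 (at least 541-fold), Cdh4 (at least 522-fold, 40.97 ± 46.01 CPM in PrES cells), Sfrp2 (at least 514-fold) and Col5a2 (-12.69 ± 1.82). The call of Tfap2b was not kept against the low-Malat1 PrES libraries (-3.30, edgeR adjusted p = 0.289).

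The PBF1 comparison set PBF1 lines labelled PrES-to-XEN against PBF1 PrES lines, with 2 line numbers on each side. Basement membrane genes rose: Lama1 from 1466 ± 131 to 25590 ± 4211 CPM (log2FC 4.13 ± 0.27, edgeR adjusted p = 6.6e-08), Lamc1 by 4.20 ± 0.30, Col4a1 from 2525 ± 23 to 32370 ± 4036 CPM (3.68 ± 0.42) and Nid1 by 4.30 ± 0.44. The basement membrane list had 15 of 19 genes called higher, 15 adjusted over the list alone (median 1.94), and the parietal endoderm list 14 of 17, also 14 adjusted over the list alone (median 3.50), with Thbd from 2.68 ± 0.499 to 317 ± 47.3 CPM (6.88 ± 0.57). For basement membrane genes, camera gave adjusted p = 9.2e-12, and adjusted p = 0.0163 with an estimated correlation. For parietal endoderm genes, camera gave adjusted p = 2.3e-14, and adjusted p = 0.0163 with an estimated correlation. Gata6 rose from 143 ± 2.51 to 703 ± 80.1 CPM (2.30 ± 0.27), Gata4 by 1.82 ± 0.17 and Foxa2 by 2.34 ± 0.25, and Fgfr2 fell by 3.46 ± 0.49. The primitive endoderm list had 6 of 15 higher and 1 lower, 8 adjusted over the list alone (median 1.16). For primitive endoderm genes, camera gave adjusted p = 0.0273, and adjusted p = 0.403 with an estimated correlation. Pou5f1 fell from 833 ± 64.1 to 0.373 ± 0.0772 CPM (-11.10 ± 0.62), Dppa5a from 1444 ± 52.9 to 4.25 ± 0.731 (-8.40 ± 0.60) and Esrrb (-9.21 ± 0.63), and 13 of 22 naive pluripotency genes were called lower and 2 higher, 16 adjusted over the list alone (median -2.50). For naive pluripotency genes, camera gave adjusted p = 1.5e-16, and adjusted p = 7.6e-04 with an estimated correlation.

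Sterol synthesis fell in PBF1 PrES-to-XEN cells: Fdft1 went from 294 ± 16.8 to 30.5 ± 4.00 CPM (log2FC -3.27 ± 0.37), Hmgcs1 from 347 ± 24.7 to 63.1 ± 10.7 (-2.46 ± 0.51) and Idi1 from 54.1 ± 5.06 to 5.42 ± 0.136 (-3.32 ± 0.50). Of 18 cholesterol synthesis genes 14 were called lower and 0 higher, 14 adjusted over the list alone (median -2.01). For cholesterol synthesis genes, camera gave adjusted p = 3.0e-08, and adjusted p = 0.414 with an estimated correlation. Feedback genes of the FGF and ERK pathway, lower as a list in CD-1 XEN cells, rose here. Dusp6 went from 0.906 ± 0.228 to 12.9 ± 1.72 CPM (3.82 ± 0.46), and Phlda1 rose by 2.83 ± 0.39. Etv5, not called in CD-1 XEN cells, rose by 2.47 ± 0.32. Of the 18 genes 8 were called higher, 8 adjusted over the list alone (median 0.88). For FGF and ERK feedback genes, camera gave adjusted p = 0.00922, and adjusted p = 0.129 with an estimated correlation, and the list was not called in a fit of the 2 groups alone (median 0.82). Germline genes such as Ddx4 (-6.70 ± 1.1) and Hormad1 (-7.30 ± 0.95) fell, 7 of 16 with 2 higher, 9 adjusted over the list alone (median -1.38). For germline genes, camera gave adjusted p = 0.0148, and adjusted p = 0.403 with an estimated correlation. The mesoderm list was not called (3 of 7 higher, 3 adjusted over the list alone, median 1.43, camera adjusted p = 0.164), and was called without PBF1 PrES line 2F (median 2.84) or PrES-to-XEN line 1F (median 2.05), with no filter or with only the 2 groups. Its endothelial cadherin Cdh5 (chromosome 8, 104101625 to 104144511) rose from 0.0266 ± 0.0376 to 112 ± 31.6 CPM (11.81 ± 1.44) and Kdr by 4.28 ± 0.96. Of 16 fibroblast genes edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 adjusted over the list alone (median 0.74, camera adjusted p = 0.679). The 2 line numbers moved apart in Col1a1, from 634 to 2456 CPM in 1F and from 1037 to 332 CPM in 2F. DESeq2 called Thy1 (2.04), and a fit of the 2 groups alone called Thy1 (2.03), Postn (-1.64) and Twist2 (4.11).

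Between the PBF1 groups 5253 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3206 higher and 2047 lower in PrES-to-XEN cells, and quantile scaling shifted the median of all genes by -0.18. Besides Cdh5, the largest increases under the rule for named genes were Myh7 (at least 870-fold), C2cd4b (at least 147-fold), Igsf1 (10.27 ± 0.99), Gkn2 (9.77 ± 1.18) and Tek (9.26 ± 0.76). The largest decreases were Tfpi2 (-11.35 ± 2.05), Pou5f1, Pramel7 (at least 208-fold lower), Tcl1 (-10.85 ± 0.95), Cdh4 (-9.53 ± 1.90) and Dppa3 (-9.51 ± 1.5).

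XEN-like cells were compared with the CD-1 PrES lines and with XEN lines, to place cells that carry Wnt3a in their names beside both types. Against PrES cells, the parietal genes rose as in XEN cells: Thbd reached 687 ± 50.3 CPM (log2FC 6.76 ± 0.34, edgeR adjusted p = 6.1e-10), Lamc1 19250 ± 1067 CPM (3.63 ± 0.18), Nid1 4715 ± 1217 CPM (3.36 ± 0.26) and Col4a1 29930 ± 928 CPM (2.88 ± 0.26). The parietal list had 13 of 17 genes higher and 2 lower, 15 adjusted over the list alone (median 2.58), and the basement membrane list 13 of 19 higher and 2 lower, 15 adjusted over the list alone (median 1.85). For parietal endoderm genes, camera gave adjusted p = 2.3e-12, and adjusted p = 0.0194 with an estimated correlation. For basement membrane genes, camera gave adjusted p = 9.6e-10, and adjusted p = 0.0272 with an estimated correlation. Pou5f1 fell to 0.939 ± 0.645 CPM (-9.32 ± 0.46), Tbx3 from 357 ± 103 to 10.3 ± 2.94 (-5.12 ± 0.29) and Nr0b1 (-11.31 ± 0.80), and 16 of 22 naive pluripotency genes were lower and 1 higher, 17 adjusted over the list alone (median -3.76). For naive pluripotency genes, camera gave adjusted p = 2.3e-10, and adjusted p = 0.00250 with an estimated correlation. The visceral list was not called (9 of 22 higher and 5 lower, 14 adjusted over the list alone, median 0.75, camera adjusted p = 0.413), with Ttr up from 0.197 ± 0.210 to 54.8 ± 25.3 CPM (8.33 ± 0.66) and Cubn down from 514 ± 90.8 to 27.1 ± 13.7 (-4.24 ± 0.30). Afp (chromosome 5, 90490737 to 90508907) was at 98.4 ± 145 CPM, a spread larger than its mean. Of 16 fibroblast genes 2 were higher and 6 lower, 8 adjusted over the list alone (median -0.73, camera adjusted p = 0.436), with Dcn (4.68 ± 0.81) higher and Prrx1 (-3.65 ± 0.57) lower. Col1a1 was not called (0.02 ± 0.75). Without XEN-like line 3, Col1a1 (-2.02) and the fibroblast list (median -2.13) were called lower.

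Cell cycle, glycolysis and FGF and ERK feedback genes were lower in XEN-like cells than in PrES and XEN cells. Against PrES cells Mki67 fell from 248 ± 30.1 to 36.7 ± 9.90 CPM (log2FC -2.76 ± 0.18) with Top2a (-2.92 ± 0.27), and 19 of 21 cell cycle genes were called lower, 19 adjusted over the list alone (median -2.23). For cell cycle genes, camera gave adjusted p = 1.5e-15, and adjusted p = 0.0903 with an estimated correlation. Glycolysis followed, Pkm from 2212 ± 406 to 238 ± 35 CPM (-3.22 ± 0.17) and Aldoa (-2.39 ± 0.15), 13 of 16 lower and 13 adjusted over the list alone (median -2.37). For glycolysis genes, camera gave adjusted p = 6.5e-11, and adjusted p = 0.0961 with an estimated correlation. Etv4 fell from 84.4 ± 18.6 to 1.35 ± 0.266 CPM (-5.97 ± 0.42), with Spry4 (-4.86 ± 0.30) and Etv5 (-4.31 ± 0.27), and the FGF and ERK list had 14 of 18 lower and 1 higher, 15 adjusted over the list alone (median -2.49). For FGF and ERK feedback genes, camera gave adjusted p = 1.5e-08, and adjusted p = 0.00250 with an estimated correlation. Dnmt3l (-5.52 ± 0.45), Tet1 (-3.86 ± 0.29) and Uhrf1 (-2.36 ± 0.24) fell, with 6 of 9 DNA methylation genes lower and 1 higher, 7 adjusted over the list alone (median -2.09). For DNA methylation genes, camera gave adjusted p = 0.00139, and adjusted p = 0.0329 with an estimated correlation. Against XEN cells all 21 cell cycle genes were lower, 21 adjusted over the list alone (median -3.46), Ccnb1 from 412 ± 4.48 to 25.4 ± 8.35 CPM (-4.02 ± 0.27). For cell cycle genes, camera gave adjusted p = 5.9e-39, and adjusted p = 0.0276 with an estimated correlation. Also against XEN cells, glycolysis had 14 of 16 lower, 15 adjusted over the list alone (median -2.32), with Gapdh (-2.53 ± 0.18). For glycolysis genes, camera gave adjusted p = 6.0e-14, and adjusted p = 0.129 with an estimated correlation. FGF and ERK feedback had 9 of 18 lower and 3 higher, 13 adjusted over the list alone (median -1.12), with Spry4 (-4.38 ± 0.32). For FGF and ERK feedback genes, camera gave adjusted p = 0.00115, and adjusted p = 0.102 with an estimated correlation. The DNA methylation list, with 4 of 9 lower and 2 higher, 6 adjusted over the list alone (median -0.90), was not called against XEN cells (camera adjusted p = 0.128) except with DESeq2 or without XEN line 2F (medians -0.72 and -0.83). Hypoxia genes had 7 of 13 lower, 7 adjusted over the list alone (median -1.47), with Egln3 (-3.74 ± 0.42) and P4ha1 (-1.98 ± 0.24), and were not called without XEN line 1M (median -0.32). For hypoxia genes, camera gave adjusted p = 0.00291, and adjusted p = 0.486 with an estimated correlation.

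Fibroblast and interferon genes were higher in XEN-like than in XEN cells. Col1a1 was at 2160 ± 2839 CPM against 2.40 ± 0.226 (log2FC 9.81 ± 1.56), Col3a1 (1305 ± 1631 CPM) was at least 16610-fold higher (fitted log2FC 17.81, and 15.99 without XEN-like line 3), and 14 of 16 fibroblast genes were called higher, 15 adjusted over the list alone (median 8.93, or 8.59 at the bound). For fibroblast genes, camera gave adjusted p = 2.9e-07, and adjusted p = 0.399 with an estimated correlation. Ddx58 rose from 1.96 ± 0.118 to 39.5 ± 14.2 CPM (4.33 ± 0.36) and Irf7 from 0.506 ± 0.315 to 24.2 ± 14.8 (5.55 ± 0.86), with 12 of 13 interferon genes higher, 12 adjusted over the list alone (median 4.33, or 4.23 at the bound). For interferon response genes, camera gave adjusted p = 1.0e-05, and adjusted p = 0.399 with an estimated correlation. The other largest increases under the rule for named genes were Prelp (at least 1001-fold, 78.7 ± 102 CPM), Fmod (at least 581-fold, 45.6 ± 64.6 CPM) and Col5a2 (12.53 ± 1.85). Without XEN-like line 3 the fitted log2FC of Prelp went from 13.75 to 11.80 and that of Fmod from 12.97 to 10.56. The largest decreases were Hist1h2ai (at least 1059-fold, with the call lost without XEN-like line 1, 3 or 4 in turn, or without XEN line 1M), Pdyn (-10.17 ± 1.71), Irf4 (-9.33 ± 1.59) and Hmga1-rs1 (-8.88 ± 1.37). All XEN libraries had low Malat1 and no XEN-like library did, so that difference and the cell type cannot be told apart here. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7122 genes were called against XEN cells (4224 higher, 59.3%) and 7076 against PrES cells (2664 higher, 37.6%). With total counts as library sizes 72.5% of 7191 calls against XEN cells were higher, and with quantile scaling 49.2% of 5517, the former shifting the median by 0.29. Quantile scaling put 49.3% of 6880 calls against PrES cells higher and shifted that median by 0.28. The largest increases against PrES cells were Gkn2 (14.33 ± 0.80), Afp (11.99 ± 1.30), Gkn1 (11.91 ± 0.88), Nat8f3 (at least 662-fold), Nell1 (at least 455-fold, 12.6 ± 18.5 CPM) and Ptger3 (10.70 ± 0.39). The fitted log2FC of Nell1 was 11.12, and 8.49 without XEN-like line 1. The largest decreases were Nr0b1, Tcl1 (-10.46 ± 0.79), Ap3b2 (-10.06 ± 1.15), Cdh4 (-10.01 ± 1.59), Alpl (-10.00 ± 0.71) and Nefl, the last with its call lost without XEN-like line 1, 3 or 4 in turn.

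The changes toward XEN in the 3 settings were compared across genes, which are not independent replicates. Pearson's r between the PBF1 changes and the CD-1 changes, which share no library, was 0.236 (Spearman's rho 0.153), and 56.2% of the 7883 genes called in CD-1 cells had the same sign in PBF1 cells. With XEN set against the low-Malat1 PrES libraries alone these became 0.299 and 67.7%. Genes called higher in both numbered 994 against 377 if independent, and genes called lower in both 908 against 587. For XEN-like and XEN cells, each against PrES, r was 0.541, and 79.1% of the XEN calls had the same sign. The shared PrES lines alone gave a mean r of 0.276 in simulated unchanged groups, and 20 splits of the PrES lines gave 0.394 to 0.533. The covariance was 2.54 against 0.0809 in the simulated groups, a difference of 2.46. With PrES libraries matched on Malat1, so that no library was shared, r was 0.497 and 84.8% of 4765 calls had the same sign, with line 5-3M on both sides at different passages. With those matched libraries 737 genes were higher in all 3 comparisons (45.8 if independent) and 597 lower (69.3 if independent). With that line also left out of the XEN-like comparison, so that no PrES line was shared, these became 0.491, 84.55%, 728 (44.1) and 596 (67.0). The change toward XEN differed between the CD-1 and the PBF1 comparison for 7663 genes, 2447 with the larger value in CD-1 and 5216 with the smaller, and 642 genes were called in opposite directions. Strain, the way the XEN state was reached and Malat1, low in all CD-1 XEN libraries and in no PBF1 library, cannot be told apart here.

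**Figure D2:**
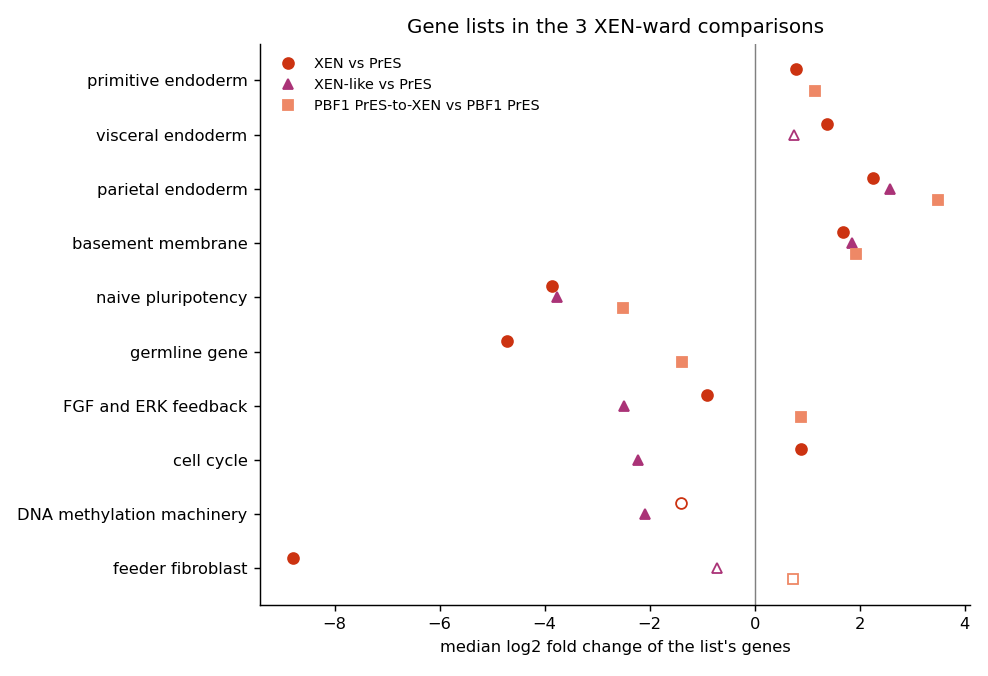
Median log2 fold change of gene lists (genes at 0 set to their bound) in 3 comparisons, with filled symbols for lists called by camera with a preset correlation and open symbols for lists not called. Parietal endoderm and basement membrane genes rose and naive pluripotency genes fell in all 3, with medians from 1.69 to 3.50 and from -3.86 to -2.50. For XEN against PrES cells the basement membrane list was not called with an estimated correlation (camera adjusted p = 0.118) or with quantile scaling (median 1.33).

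On the line from the CD-1 PrES mean (0) to the XEN mean (1), with each line left out of its own reference, PrES lines sat at 0.0218 ± 0.105, PBF1 PrES lines at 0.225 ± 0.0255, PBF1 PrES-to-XEN lines at 0.428 ± 0.0431, XEN-like lines at 0.484 ± 0.0914 and XEN lines at 0.901 ± 0.0154. The 2 PrES libraries at passages 20 and 21, which also had low Malat1, sat at 0.192 and 0.199, and the others between -0.0744 and 0.00553. By this position, XEN-like lines and PBF1 PrES-to-XEN lines were nearer to each other than either was to the XEN lines. All XEN libraries had low Malat1 and no library of those 2 groups did, so Malat1 level and cell type cannot be told apart in that gap.

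**Figure D3:**
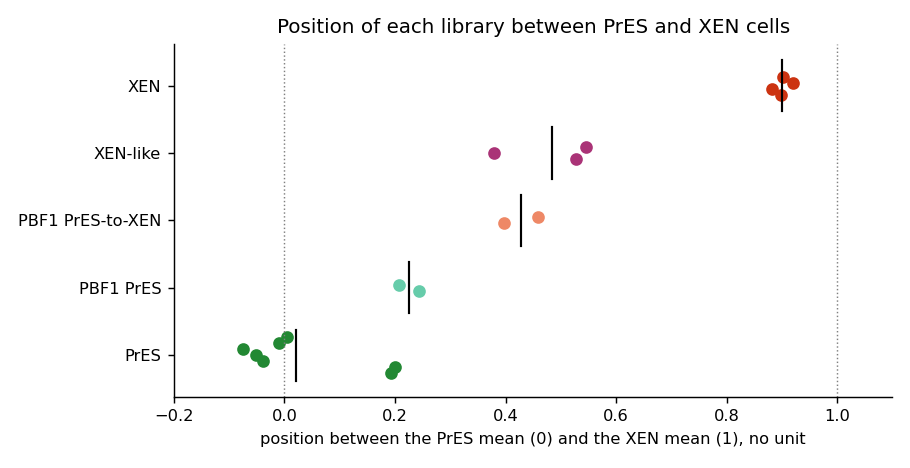
Position of each library (point) between the CD-1 PrES mean at 0 and the XEN mean at 1, with the mean per type as a black line. PBF1 PrES-to-XEN and XEN-like libraries sit between 0.379 and 0.545, and XEN libraries between 0.882 and 0.921.

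ES cells were compared with PrES cells as the epiblast counterpart, with the ES lines from another strain than the PrES lines and all in media named 2iL. Endoderm genes were lower in ES cells: Gata4 fell by 6.23 ± 0.21 on the log2 scale (edgeR adjusted p = 1.6e-11), followed by Gata6 (-8.15 ± 0.35), Sox17 (-8.08 ± 0.40) and Pdgfra (-7.68 ± 0.45), with 12 of 15 primitive endoderm genes lower, 13 adjusted over the list alone (median -6.23). For primitive endoderm genes, camera gave adjusted p = 2.3e-26, and adjusted p = 2.1e-05 with an estimated correlation. Col4a1 (-6.93 ± 0.48), Lamb1 (-5.01 ± 0.37) and Serpinh1 (-3.98 ± 0.15) fell, while Nid1 was not called (0.11 ± 0.31). The parietal list had 14 of 17 lower and 1 higher, 15 adjusted over the list alone (median -3.23), and the basement membrane list 12 of 19 lower, 12 adjusted over the list alone (median -2.23). For parietal endoderm genes, camera gave adjusted p = 1.0e-12, and adjusted p = 0.0180 with an estimated correlation. For basement membrane genes, camera gave adjusted p = 1.5e-10, and adjusted p = 0.0180 with an estimated correlation. Cubn fell from 514 ± 90.8 to 0.190 ± 0.0305 CPM (-11.35 ± 0.53) with Lrp2 (-5.77 ± 0.52), and 9 of 14 endocytosis receptor genes were lower, 9 adjusted over the list alone (median -2.49). For endocytosis receptor genes, camera gave adjusted p = 4.1e-10, and adjusted p = 0.00814 with an estimated correlation. The visceral list had 10 of 22 lower and 3 higher, 14 adjusted over the list alone (median -1.70), with Ihh (-7.41 ± 0.67). For visceral endoderm genes, camera gave adjusted p = 0.00797, and adjusted p = 0.406 with an estimated correlation. Nanog rose by 8.51 ± 0.29, Klf2 by 6.61 ± 0.36 and Sox2 by 6.58 ± 0.55, Pou5f1 did not pass the threshold (0.68 ± 0.30, edgeR adjusted p = 0.0747), and 14 of 22 naive genes were higher, 14 adjusted over the list alone (median 1.94). For naive pluripotency genes, camera gave adjusted p = 9.2e-12, and adjusted p = 0.00354 with an estimated correlation.

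Fgf4 (chromosome 7, 144847367 to 144865243) went from 0.0101 ± 0.0246 CPM in PrES to 300 ± 71.4 CPM in ES cells (log2FC 14.29 ± 0.64), the largest increase under the rule for named genes, while feedback genes of the pathway fell: Dusp4 (-3.77 ± 0.33), Spry4 (-3.65 ± 0.32) and Phlda1 (-3.82 ± 0.38), with Etv5 up by 2.54 ± 0.21. Of 18 FGF and ERK genes 10 were lower and 2 higher, 13 adjusted over the list alone (median -1.88). For FGF and ERK feedback genes, camera gave adjusted p = 6.3e-04, and adjusted p = 0.0367 with an estimated correlation. All ES libraries were in media named 2iL, so an effect of the medium on these genes cannot be told apart from cell type. Primed epiblast genes Otx2 (5.21 ± 0.59) and Foxd3 (6.79 ± 0.65) rose and Dnmt3b fell by 2.10 ± 0.36, 5 of 9 higher and 2 lower, 7 adjusted over the list alone (median 2.40). That list was not called without ES line 1M or PrES line 6-5M or 7-2M (medians 2.33, 2.45 and 2.47), nor under 6 other alternatives. For primed epiblast genes, camera gave adjusted p = 0.0334, and adjusted p = 0.265 with an estimated correlation. Fibroblast genes were lower in ES cells for 13 of 16, 14 adjusted over the list alone (median -3.54), with Col6a3 (-6.74 ± 0.80). For fibroblast genes, camera gave adjusted p = 0.00265, and adjusted p = 0.430 with an estimated correlation. In all, 6644 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2932 higher and 3712 lower, and total-count and quantile scaling shifted the median of all genes by 0.13 and 0.11. The other named genes were Slc6a7 (at least 1371-fold), Dmrt1 (at least 649-fold), Mcf2 (11.55 ± 0.55), Spic (at least 494-fold, call lost in DESeq2) and Ildr1 (10.40 ± 0.55) upwards, and Habp2 (-11.39 ± 1.57), S100g (-11.38 ± 1.87), Tcf23 (-10.05 ± 0.64), Adora1 (-9.20 ± 0.54) and P3h2 (-8.70 ± 0.62) downwards.

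TS cells were compared with PrES cells as the trophoblast counterpart, with 2 of the 6 labelled TS libraries available. Elf5 (chromosome 2, 103411688 to 103450989) rose from 0.0524 ± 0.0346 to 458 ± 154 CPM (log2FC 13.10 ± 0.36, edgeR adjusted p = 5.5e-13), Tfap2c by 9.32 ± 0.22, Hand1 by 9.56 ± 0.36, Cdx2 by 7.40 ± 0.55 and Eomes by 7.45 ± 0.53. Of 20 trophoblast stem cell genes 18 were higher, 18 adjusted over the list alone (median 4.21), and of 9 genes of differentiated trophoblast 5 were higher, 5 adjusted over the list alone (median 3.6), with Prl3d1 at 31 ± 6.32 CPM. For trophoblast stem cell genes, camera gave adjusted p = 1.6e-24, and adjusted p = 2.3e-06 with an estimated correlation. For differentiated trophoblast genes, camera gave adjusted p = 0.0154, and adjusted p = 0.0494 with an estimated correlation. Epithelial genes rose in 15 of 18 cases, 15 adjusted over the list alone (median 2.89), Cldn3 by 10.78 ± 0.48 and Krt8 by 2.49 ± 0.25. For epithelial genes, camera gave adjusted p = 1.1e-11, and adjusted p = 0.0494 with an estimated correlation. BMP targets Smad6 (5.24 ± 0.37) and Smad7 (2.47 ± 0.25) rose, 8 of 12, 8 adjusted over the list alone (median 1.85). For BMP target genes, camera gave adjusted p = 2.0e-04, and adjusted p = 0.0187 with an estimated correlation. Kdr (7.42 ± 0.58) and Gata1 (8.65 ± 0.84) rose among 7 mesoderm genes, 6 higher and 7 called adjusted over the list alone (median 5.10). For mesoderm genes, camera gave adjusted p = 2.6e-04, and adjusted p = 0.0187 with an estimated correlation. Primitive endoderm genes were lower in 10 of 15 cases and higher in 2, 12 adjusted over the list alone (median -4.23), with Sox17 (-10.33 ± 0.50) and Gata4 (-3.81 ± 0.18). For primitive endoderm genes, camera gave adjusted p = 7.8e-16, and adjusted p = 0.00221 with an estimated correlation. Naive pluripotency genes divided: Sox2 rose from 5.69 ± 3.89 to 576 ± 144 CPM (6.63 ± 0.55), and Klf4 (-3.93 ± 0.31) and Tbx3 (-5.39 ± 0.36) fell, 12 of 22 lower and 7 higher, 19 adjusted over the list alone (median -1.32, and not called without TS line 1F at a median of -0.97). For naive pluripotency genes, camera gave adjusted p = 0.00393, and adjusted p = 0.0737 with an estimated correlation. The imprinted list was not called (12 of 29 higher and 5 lower, 17 adjusted over the list alone, median 0.55, camera adjusted p = 0.118), and was called without TS line 1F (median 0.80), with no filter, by camera on DESeq2 values and with only the 2 groups. H19 rose from 188 ± 137 to 11660 ± 3473 CPM (5.96 ± 0.72), Igf2 by 5.88 ± 0.85 and Cdkn1c by 7.41 ± 0.71.

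Fibroblast genes were lower in TS cells for 7 of 16, 7 adjusted over the list alone (median -1.58), and the list was not called (camera adjusted p = 0.0512). It was called with no filter, with median-ratio or quantile scaling, without trend and robust steps, by camera on DESeq2 values, with only the 2 groups and against the low-Malat1 PrES libraries (medians -1.58 to -1.55). It was also called without TS line 1F (median -2.34) and without PrES line 5-3M, 8-2M or 8-3F (medians -1.52, -1.67 and -1.62). In all, 6796 genes were called between TS and PrES cells by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2653 higher (39.0%), and 4520 against the low-Malat1 PrES libraries alone, 53.6% of them higher. Besides Elf5 the named genes were Prss50 (at least 2325-fold), Ctsj (at least 2049-fold, 56.8 ± 67.1 CPM in TS cells, with log2FC 10.68 without TS line 8M and 14.19 without 1F), Tmem114 (12.27 ± 0.57), Rhox4g (11.51 ± 0.81) and Fgfbp1 (11.12 ± 1.00) upwards. Those downwards were Aqp8 (at least 1706-fold), Klb (at least 1087-fold), Habp2 (at least 899-fold), Tcl1 (at least 283-fold), Bpifb5 (at least 247-fold) and Fam151a (at least 192-fold).

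The 2 XEN media were compared in the same 2 lines. No gene was called between Serum/C3L and Serum/L by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while 1046 of 19289 had an unadjusted p under 0.05, DESeq2 called 16 with Axin2 (2.64) and Adm (4.84) among them, limma on quantile-scaled values called 3, and a fit with the line as a block called 1. Without the Serum/C3L library of line 2F 78 genes were called, among them Adm (5.76) and Pdk1 (2.12). Axin2 was at 6.37 ± 4.97 CPM in Serum/C3L and 1.02 ± 0.151 in Serum/L (log2FC 2.63 ± 0.68, edgeR adjusted p = 0.662), and 1 of 17 Wnt targets passed when adjusted over the list alone (median 0, camera adjusted p = 0.596, with the list called in a fit of the 2 groups alone). Hypoxia genes such as Adm (4.81 ± 1.23) and Pdk1 (1.39 ± 0.45) had higher values in Serum/C3L, with 0 of 13 called by edgeR, 1 by DESeq2, 4 at an unadjusted p under 0.05 and 4 adjusted over the list alone (median 0.64). For hypoxia genes, camera gave adjusted p = 5.6e-04, and adjusted p = 0.533 with an estimated correlation. The cholesterol synthesis list had a median of 0.52 with 0 of 18 called by edgeR or DESeq2, 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 5.2e-04, and adjusted p = 0.756 with an estimated correlation), led by Dhcr7 (0.96 ± 0.48). Both medians rested on 1 library: without the Serum/C3L library of line 1M they were -0.32 for hypoxia and -0.15 for cholesterol synthesis. Visceral genes had a median of -0.996 (camera adjusted p = 0.00340, and adjusted p = 0.541 with an estimated correlation) and mesenchymal genes of -0.79 (camera adjusted p = 5.2e-04, and adjusted p = 0.533 with an estimated correlation), with 0 of 22 and 0 of 16 called by edgeR and by DESeq2, 4 and 3 at an unadjusted p under 0.05, and 0 adjusted over the list alone in both. The visceral list was not called without the Serum/L library of line 1M (median 0.39) or the Serum/C3L library of line 2F (median -0.67), nor the mesenchymal list without the Serum/C3L library of line 1M (median -0.63).

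The 2 ES media were likewise compared in 2 lines. Fibroblast genes were the clearest difference. Col1a1 was at 306 ± 90.3 CPM in FBS/2iL and 2.17 ± 1.31 in NB/2iL (log2FC -7.13 ± 1.32, edgeR adjusted p = 0.00369), Col1a2 at 217 ± 115 and 0.184 ± 0.126 (-10.13 ± 1.46) and Prrx1 at 30.4 ± 8.77 and 0.210 ± 0.0398 (-7.13 ± 0.97). Of 16 fibroblast genes 10 were lower in NB/2iL, 15 adjusted over the list alone (median -4.96). For fibroblast genes, camera gave adjusted p = 1.8e-18, and adjusted p = 0.138 with an estimated correlation. Mesenchymal genes followed with 8 of 16 lower, 12 adjusted over the list alone (median -2.44), Mmp14 (-3.02 ± 0.49). For mesenchymal genes, camera gave adjusted p = 9.5e-09, and adjusted p = 0.190 with an estimated correlation. The parietal list had 5 of 17 lower and 1 higher, 9 adjusted over the list alone (median -0.66), with Col4a1 at 57.0 ± 1.79 and 10.7 ± 1.89 CPM (-2.41 ± 0.39). For parietal endoderm genes, camera gave adjusted p = 0.00159, and adjusted p = 0.587 with an estimated correlation. Germline genes had 3 of 16 lower, 9 adjusted over the list alone (median -1.88), with Sycp3 (-2.0 ± 0.52). For germline genes, camera gave adjusted p = 3.4e-05, and adjusted p = 0.190 with an estimated correlation. Among naive pluripotency genes 1 of 22 was called, 1 adjusted over the list alone (median -0.11, above 0 with total-count or quantile scaling, camera adjusted p = 0.969), with Klf5 at 181 ± 19 against 67.9 ± 4.38 CPM (1.42 ± 0.26) and Nanog not called (-0.96 ± 0.34). Zrsr1 was the imprinted gene that rose, from 31.3 ± 7.03 to 221 ± 14.5 CPM (2.83 ± 0.20, edgeR adjusted p = 9.2e-08), and the imprinted list had 1 of 29 higher and 2 lower, 4 adjusted over the list alone (median 0.08, camera adjusted p = 0.441).

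Between the ES media 827 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 198 higher (23.9%) and 629 lower in NB/2iL. The count fell to 229 without the NB/2iL library of line 1M, 296 without that of line 6M and 383 without the FBS/2iL library of line 6M, and the calls of Col1a1, Sdpr, Lyz2 and Sycp3 were lost without the NB/2iL library of line 1M or of line 6M. Lyz2 also lost its call without the FBS/2iL library of line 6M, and Sycp3 without that of line 1M. Klf5 and Rgma lost their calls without either library of line 6M, and the parietal list without the NB/2iL library of line 1M (median -0.29). Col1a2, Prrx1 and Zrsr1 kept their calls without each library in turn. With total counts as library sizes 35.8% of 801 calls were higher, with a median shift of 0.12, and with quantile scaling 41.7% of 1214. The other named genes were Gata2 (3.27 ± 0.90), Rgma (3.02 ± 0.62) and Ripply3 (2.79 ± 0.80) upwards, and Lyz2 (at least 459-fold, 32.1 ± 44.8 CPM in FBS/2iL), Cav1 (at least 451-fold), Wisp2 (at least 390-fold) and Sdpr (at least 238-fold) downwards. The fitted log2FC of Lyz2 was -12.12, and -5.96 without the FBS/2iL library of line 6M. The calls of Gata2 and Ripply3 were lost without any 1 of the 4 libraries.

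Levels of marker RNAs in single libraries differed in ways the groups did not fully explain. Malat1 was between 83.2 and 333 CPM in the TS libraries, the PrES libraries at passages 20 and 21 and all XEN libraries, and at 446 CPM or more in the other 16. The low-Malat1 libraries also had the lowest total counts, at most 13602247 against at least 14792172 in the other 16. They had the fewest genes detected as well, at most 20098 against at least 22186. Col1a1 ranged from 283 to 5655 CPM among XEN-like libraries and from 976 to 3248 CPM among PrES libraries. Xist (chromosome X, 103460366 to 103483254) was at 1134 and 1889 CPM in the 2 PrES libraries whose line names end in F, where Ddx3y was at 10.6 and 10.9 CPM. Among the 5 whose names end in M it was at 3.32 and 10.8 CPM at passages 20 and 21, and at 391, 370 and 388 CPM in lines 8-2M, 5-3M at passage 38 and 7-2M, where Ddx3y was at 73.7, 22.2 and 33.1 CPM. XEN line 1M had Xist at 0.400 and 0.243 CPM and Ddx3y at 2.80 and 0.567 CPM. TS line 8M had Ddx3y at 5.73 CPM and Xist at 2.79 CPM, and TS line 1F had Ddx3y at 11.2 CPM and Xist at 265 CPM. Prnp (chromosome 2, 131909928 to 131938429) took between 1.08% and 4.38% of all counts in PrES libraries. Its mean over libraries, without TMM factors, was 26350 CPM in PrES, 1033 in XEN and 104 in ES cells.

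**Figure D4:**
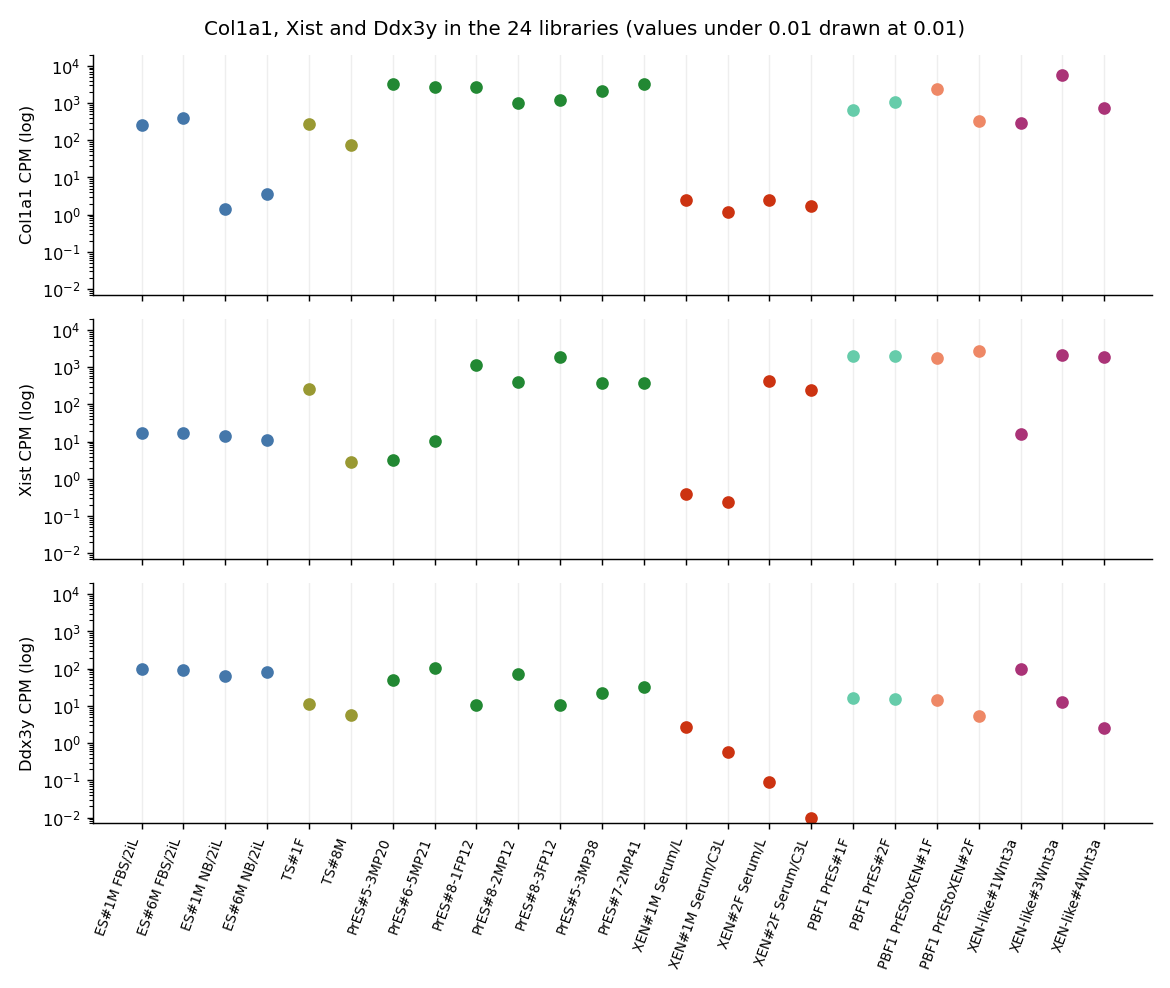
CPM (log axis) of Col1a1, Xist and Ddx3y in each of the 24 libraries, 1 point per library, coloured by cell type. The XEN and ES NB/2iL libraries lie at or below 3.59 CPM for Col1a1, and 3 PrES libraries with M in their names show Xist and Ddx3y together.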

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

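The tests of the low-Malat1 libraries, of the Xist to Col1a1 ratio, of a mix of female and male cells and of shared 31-mers were chosen only after the result was seen, and the test of feeder RNA was written before.

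Single libraries stood apart in 3 of 60 lead genes tested by Dixon's criterion in the 7 PrES libraries, where 3 were expected by chance, and in 0 of 10 library measures. PrES line 7-2M at passage 41 had the lowest Zfp42 (5.488 log2 CPM, nearest 5.862) and Ddx4 (1.069, nearest 2.743), and PrES line 8-2M the lowest Lrp2 (7.109, nearest 8.299). About 1 in 20 such tests passes by chance, and no cause was tested.

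The change toward XEN ran in opposite directions in the CD-1 and PBF1 comparisons for 6 of the 144 named genes, with the difference itself tested as an interaction in edgeR. Fn1 changed by -4.41 in CD-1 and 1.90 in PBF1 lines (difference -6.309 ± 0.712, adjusted p = 3.1e-05). Ifih1 rose by 3.00 in PBF1 lines and was at 0 in XEN lines (fitted difference -12.47 ± 1.5, adjusted p = 5.4e-05), and its call in PBF1 lines was lost without PBF1 PrES line 2F (2.71). Irf7 changed by -2.79 and 3.66 (-6.456 ± 1.09, adjusted p = 3.4e-04), with the CD-1 call lost without XEN line 2F (-2.28) and with quantile scaling (-0.92). Oas1a changed by -3.27 and 4.39 (-7.663 ± 0.966, adjusted p = 5.7e-05), Fosl1 by -5.68 and 2.52 (-8.204 ± 0.848, adjusted p = 1.9e-05) and Spred3 by -3.68 and 1.52 (-5.203 ± 0.596, adjusted p = 3.1e-05). The fibroblast list was lower in CD-1 XEN cells for 16 of 16 genes (median -9.82). It was not called in PBF1 lines (median 0.74), where Col1a1 rose in line 1F and fell in line 2F. Malat1 was low in all CD-1 XEN libraries and in no PBF1 library. For the fibroblast list the Malat1 split does not account for the fall, since the median was -9.075 against the 2 PrES libraries of low Malat1. Strain was confounded with the way the XEN state was reached and, for the 6 genes, with Malat1, so these cannot be told apart.

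Fibroblast genes were far lower in XEN than in PrES libraries, with Col1a1 at 976 to 3248 CPM in PrES and 1.2 to 2.5 CPM in XEN libraries. The split on Malat1 does not account for this, since against the 2 PrES libraries of low Malat1 the median of the list was -9.0752, with 15 of 16 genes lower. RNA from feeder fibroblasts in the PrES cultures may contribute. Of 609 genes lower in ES cells in NB/2iL than in FBS/2iL, outside the fibroblast and mesenchymal lists, 33.99% were lower in XEN cells (95% exact interval 30.2 to 37.9), against 28.7% of all genes and 25.9% of genes matched for abundance. The interval reaches past the bound of 35% set before, so this test cannot tell feeder RNA from fibroblast-like gene expression of PrES cells themselves. The labels name neither feeders nor a sorting step. PrES lines 8-1F and 8-3F, with Col1a1 at 2665 and 1173 CPM, had Y-linked Uty at 3.92 and 3.97 CPM. XEN line 2F, with Col1a1 at 2.43 and 1.73 CPM, had Uty at 0 in both media. If the names are right, those PrES cultures held RNA of male cells. Uty did not follow the level of Col1a1, since TS line 1F had 4.37 CPM with Col1a1 at 273 CPM. How much Col1a1 came from such cells was not tested, so both sources stay open. One of the 16 genes, Twist1, was also on the mesenchymal list.

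Xist and Y-linked RNA appeared together in 3 PrES libraries whose names end in M. The ratio of Xist to Col1a1 spanned 390.47-fold over the 5 male-named PrES libraries while that of Col1a2 to Col1a1 spanned 1.45-fold. The span came from the libraries at passages 20 and 21 (0.00103 and 0.00391), and in the 3 with Xist the ratio lay between 0.119 and 0.401. If Col1a1 came from feeders alone, which cannot be told here, this argues against 1 feeder stock with Xist in all 5 libraries. It does not argue against such a stock in those 3. A mix of female with male cells could give both RNAs: the Xist share plus the Y-linked share came to 1.70, 0.578 and 0.768 in lines 8-2M, 5-3M and 7-2M (median 0.76802), where a mix needs a sum near 1. The Y-linked share held a background, since the mean Y-linked level in the 2 PrES libraries named F was 22.3% of that in the 2 male-named libraries of low Xist, and with it removed the sums were 1.88, 0.385 and 0.631. The 2 male-named libraries used as the reference differed, with Ddx3y at 50.5 CPM in line 5-3M at passage 20 and 104 CPM in line 6-5M. The sums therefore depend on that reference, and line 5-3M was on both sides. Against the mean of the reference the sums lie on both sides of the range set for a mix. A mix, feeder RNA in those 3 libraries, a wrong name and expression of Xist in male cells therefore cannot be told apart, and no biological explanation was tested.

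Prnp rose and fell across libraries together with 16 other symbols of over 5 CPM (correlation of at least 0.9). Reads shared with Prnp are a candidate explanation for part of them. Of 13 of these symbols found in the annotation, 5 share 31-mers with Prnp transcripts (Gm11127, Wdr31, Gm19757, Gm14149 and Trpc6), against 34 of 55340 genes in all (Fisher's exact test, two-sided, p = 8.25e-14). The symbols were picked from 11355 of at least 5 CPM, but set against all annotated genes, so the p-value does not measure enrichment among genes that could be picked. The other 8, such as Gm10845 and Kcnh6, share 0, and for those and for the level of Prnp itself the cause stays open.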

How the results depend on the processing

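Chosen only after the result was seen were the filter on mean CPM of at least 5, total-count scaling, quantile scaling with limma, the PrES libraries grouped by Malat1 and the set without genes that follow the fibroblast level.

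With the CPM filter, which tests fewer genes, calls numbered 3262 for XEN against PrES, 3344 for ES, 3056 for TS and 4096 for XEN-like against PrES, and 3611 for XEN-like against XEN cells. With only the 2 PrES lines of low Malat1, and so fewer samples, they were 4765 for XEN and 4520 for TS cells. DESeq2 called 1255 genes between the ES media and 16 between the XEN media, where quantile scaling with limma called 3. The concordance of the changes toward XEN was 0.320 with the CPM filter and 0.339 with quantile scaling, and that of XEN-like with XEN cells 0.622 with quantile scaling. The causes were not tested.

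The line as a replicate block gave 1 call between the XEN media and 828 between the ES media, 5030 between the PBF1 groups and a concordance of 0.241. With it T in the PBF1 comparison (4.08) and Vim in the ES media (-2.13) lost their calls and Snai1 in the ES media gained one (-1.26), and it changed no other call among the named genes and lists.

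On the line from PrES to XEN, a prior count of 0.1 placed XEN lines at 0.852, PBF1 PrES at 0.180, PBF1 PrES-to-XEN at 0.298 and XEN-like lines at 0.356. Quantile scaling placed them at 0.874, 0.256, 0.587 and 0.629. The CPM filter placed XEN lines at 0.920 and PBF1 PrES-to-XEN lines at 0.4934. With the PrES end from the low-Malat1 libraries XEN lines sat at 0.885 and PBF1 PrES lines at 0.190.

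With 1 line or library left out, calls ranged from 6193 to 8342 for XEN against PrES, 5089 to 6974 for ES, 5070 to 7313 for TS, 6106 to 7150 for XEN-like against PrES, 5723 to 6816 for XEN-like against XEN, 3993 to 4338 for PBF1, 0 to 78 for the XEN media and 229 to 851 for the ES media. The concordances ranged from 0.175 to 0.257 and from 0.4996 to 0.582. Positions ranged from 0.898 to 0.907 for XEN, 0.207 to 0.256 for PBF1 PrES, 0.398 to 0.459 for PBF1 PrES-to-XEN and 0.453 to 0.536 for XEN-like lines.

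The direction of a gene, or the camera direction of a list, called in either setting changed for 2 genes and 2 lists. Thbd in ES against PrES cells was -3.93 with the NB/2iL libraries alone. With 1 line or library left out, Col1a1 in XEN-like against PrES cells went from -2.02 to 0.65, and in the XEN media the median of cholesterol synthesis genes from -0.15 to 0.92 and of hypoxia genes from -0.32 to 1.203. Medians of 2 other lists with a call changed sign as the call was lost, to 0.39 for visceral genes in the XEN media without the Serum/L library of line 1M and to -0.27 for epithelial genes in XEN against PrES cells without XEN line 1M.

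Of 9538 values for 527 genes 192 lost the call and 48 gained one, and 431 genes kept the direction and side of the threshold under every alternative that gave a value. Of 1407 values for 77 lists 39 lost and 24 gained the call, and 52 lists kept their side. Quantile scaling with limma lost the calls of primitive endoderm, basement membrane, unfolded protein response and epithelial genes in XEN against PrES cells, of primed epiblast genes in ES cells, of primitive endoderm genes in the PBF1 comparison and of hypoxia genes in the XEN media. The CPM filter lost those of primitive endoderm and epithelial genes in XEN cells, of primed epiblast genes in ES cells, of primitive endoderm, unfolded protein response and interferon genes in the PBF1 comparison and of visceral genes in the XEN media. Leaving out 1 line or library accounted for 119 of the lost calls of genes and lists, and quantile scaling for 25. The alternatives on TPM, with 0.1 and 5 as added values and filters on mean TPM, were not run because the file held counts, and a gene absent after a filter gave no value.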

Other observations

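The tests of ribosomal protein genes were chosen only after the result was seen, while the tests of gene lists and the splits of the lines were planned.

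Of 3 further gene lists in the changes toward XEN, none was called in any of them with an estimated correlation, and the calls below rest on the preset one. Unfolded protein response genes, higher in XEN than in PrES cells, were also higher in XEN-like cells (9 of 15 and 1 lower, 10 adjusted over the list alone, median 1.06, camera adjusted p = 0.00188, 0.411 with an estimated correlation), with Herpud1 (1.77 ± 0.24), Atf4 (1.26 ± 0.18) and Creld2 (1.31 ± 0.18). In PBF1 PrES-to-XEN cells 7 of 15 were higher and 1 lower, 8 adjusted over the list alone (median 1.01, camera adjusted p = 0.0273, 0.521 with an estimated correlation), and the list was not called without PBF1 PrES-to-XEN line 2F (median 0.87). In XEN-like cells 9 of 18 epithelial genes were higher and 1 lower, 10 adjusted over the list alone (median 1.25, camera adjusted p = 0.00139, 0.434 with an estimated correlation): Krt8 rose by 3.36 ± 0.23 and Krt18 by 2.39 ± 0.37. The lower gene was Cdh1 (-1.05 ± 0.39), whose call was lost under 14 alternatives, among them median-ratio scaling (-0.91), DESeq2 (-0.91) and the omission of XEN-like line 1 (-0.79) or 3 (-0.66) or of PrES line 5-3M, 7-2M, 8-1F, 8-2M or 8-3F (-1.0026 to -0.87). In XEN cells 7 of 18 were higher and 2 lower, 10 adjusted over the list alone (median 0.53, camera adjusted p = 0.0377, 0.548 with an estimated correlation), with Krt8 up by 3.40 ± 0.25 and Cdh1 (-2.42 ± 0.50) lower. That list was not called without XEN line 1M (median -0.27) or PrES line 5-3M, 6-5M or 7-2M (medians 0.51, 0.50 and 0.81), with only the Serum/C3L libraries of XEN (median 0.51) or with only PrES libraries up to passage 21 (median 0.84). In PBF1 PrES-to-XEN cells 0 of 18 epithelial genes were higher and 3 lower, 3 adjusted over the list alone (median -0.18, camera adjusted p = 0.286). Interferon response genes, lower in XEN than in PrES cells, were higher in PBF1 PrES-to-XEN than in PBF1 PrES cells for 6 of 13, 6 adjusted over the list alone (median 2.18, camera adjusted p = 0.0273, 0.521 with an estimated correlation), with Stat1 (2.73 ± 0.48) and Oas1a (4.39 ± 0.69). Between XEN-like and PrES cells 3 were higher and 4 lower, 7 adjusted over the list alone (median -0.05, camera adjusted p = 0.552). The directions of the medians of the lists called here held under median-ratio, total-count and quantile scaling.

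The low level of cell cycle genes in XEN-like cells came with low ribosomal protein RNA. Of 78 ribosomal protein genes 75 were called lower than in PrES cells, with a median of -1.84 (quartiles -2.13 and -1.64) and of -1.70, -1.88 and -1.77 under median-ratio, total-count and quantile scaling. All symbols that start with Rps or Rpl and a digit, a wider set than these 78 genes, took 1.99% to 2.12% of counts in XEN-like libraries. In the other 21 libraries they took 4.28% to 12.1%. The XEN-like lines carry Wnt3a in their names, and neither a growth state nor an effect of Wnt3a was tested against the other.

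The 9 lines of XEN-like and PrES cells were split into 3 and 6 in 84 ways. Only 1 split, the real one, gave as many genes (6071 in a fit of those lines alone), and the highest of the others gave 20. Every other split put XEN-like and PrES lines together in 1 group. That widens the spread within groups, so few calls there were fixed beforehand and the splits do not settle whether chance gave the calls.

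Malat1 split the libraries by cell type except among PrES cells. All TS and XEN libraries and the 2 PrES libraries at passages 20 and 21 were low, and no ES, PBF1 or XEN-like library was. The low-Malat1 libraries had the lowest total counts and the fewest genes detected, so Malat1 level and depth cannot be told apart. XEN cells were therefore also compared with those 2 PrES libraries alone, where 40.3% of the 4765 calls were higher, against 29.1% of 7883 with all PrES lines.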
